A study of Homo sapiens with 6 samples.

How the data were processed

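Total RNA (500 ng per sample) from A2780 cells grown with 10% serum was labelled with biotin and hybridised to Illumina bead arrays, per the labels' protocols. The 6 arrays fall into 2 groups of 3, parental and SINE-resistant, taken from the sample titles together with the growth protocol. The labels give no batch.

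The authors deposited a table of non-normalized signal intensity with 47231 probes and no detection p-values or control probes. Its lowest values, 74.4 to 93.0, show that no background had been subtracted. The submitters' processing notes name GenomeStudio, and its version, scanner settings and the summary of beads into probes are not given in the sources used here. The authors also deposited a table of log2 values of the same probes. Its 6 columns have identical sorted values, so they are quantile normalized, with a median of 6.92 in each column. Each column follows the order of its array's signal intensity, so scale and direction are settled from the values, while the constant behind its lower end stays unknown.

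The probe identifiers of the signal intensity table were repaired. In its first 6554 rows the identifiers run up by 1 from row to row, as a filled spreadsheet column does. Each row was matched to the log2 table by its values on all 6 arrays. All 47231 rows matched one-to-one within a distance of 0.001 on the log2 scale, and the second-best match of any row was at least 0.0084 away. The deposited identifier was right in 1 of the first 6554 rows and in all 40677 later rows, so 6553 rows (13.87%) were renamed. Rows of the first part are sorted by gene symbol under the matched identifiers (87.7% of neighbours in order) and not under the deposited ones (49.1%).

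Gene names came from the platform annotation given for the array. It gives 1 symbol for 30113 probes and several for 8, and leaves 17110 unnamed here. Entrez identifiers linked 30074 of the named probes to RefSeq genes (assembly GRCh38.p14, used for names, gene lengths and neighbour order only, since the files name no build), and 39 kept the platform's symbol. These probes name 20046 genes. Several list members are not among them and are not analysed here.

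The planned method (neqc) needs detection p-values, so a method without them was used. In limma 3.58.1 (R 4.3.3, with package data.table at 1.17.8), signal intensities were background corrected with normexp (saddle-point estimate, offset 16), quantile normalized and put on the log2 scale. A detection p was estimated per probe and array from a normal distribution around the mode of the array's signals, with the spread of the signals below the mode. This background was 97.7 to 118.6 with an SD of 5.52 to 7.03. Named probes with an estimated detection p under 0.05 on at least 3 arrays were kept (17110, by chance the same number as the unnamed probes), and the brightest probe stood for each of 12590 genes. Of these genes, 3530 had several kept probes, and 37 called genes had another probe called in the opposite direction. Fold changes are on the background-corrected scale with the offset, which understates changes of dim genes.

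Groups were compared with lmFit and eBayes in limma, without covariates, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The 32 gene lists were fixed before the data were examined, and the 30 lists with at least 5 genes tested were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists). The rule for named genes was fixed at the same time. It takes the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap, up to 4 called members per list with the largest change, and a fixed set of genes that includes XPO1, CDKN1A, MDM2, NRG1, ERBB2, ERBB3, EGFR and ABCB1, wherever measured. A gene below background on every array of a group has a bound only. The bound sets the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the lowest normalized signal above background and the probe's own value. Printed levels are measured means.

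The test was tried on simulated arrays with the real arrays' means and a noise SD of 0.22. For the simulated comparison of the groups (12032 genes tested), it recovered 98% of 98 genes changed 2-fold and 35.8% of 95 genes changed 1.5-fold, and called 8 of 11809 unchanged genes. A planted list of 30 genes, all raised 2-fold, was called and 0 of 29 other lists were. Few other genes changed in the simulation, whereas 43.6% of the genes were called in the real data. The list test was thus not tried with smaller shifts or against such a background. The changed genes were drawn from brighter genes, and the noise was independent between genes. The recovery therefore does not cover dim genes. The result for lists does not cover correlated members, and the estimated correlation within the real lists reached 0.47.

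Alternatives were other background corrections and scalings, the authors' log2 values, other filters and probe rules, other variance models, array weights, an offset of 50, the replicate number as a block, each array left out in turn, and other set tests. Scaling to the 75th percentile and the deposited identifiers were added after the data were seen, and the ranges of adjusted p and the counts of 19 alternatives leave out the deposited identifiers. Preparation and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.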

Results

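Transcript levels were measured in A2780, an established human ovarian cancer cell line, with Illumina bead arrays. The parental line was compared with a SINE-resistant derivative, each on 3 arrays. SINE stands for selective inhibitor of nuclear export, a drug class that blocks the export receptor XPO1. Per the labels' series design, both groups were exposed to the drug for 24 h before RNA was extracted, and no drug-free array was analysed here. The titles call the resistant arrays only SINE, and the growth protocol names the parental and SINE-resistant cells. The labels do not state whether the replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The median probe signal was 123.1, 117.8 and 109.1 on parental arrays 1 to 3 and 106.5 and 127.9 on resistant arrays 1 and 3, with resistant array 2 within 0.1 of array 3. This median lay near the estimated background. The upper decile of signals began at 747.6, 687.1 and 849.7 on parental arrays 1 to 3. It began higher on every resistant array, at 917.9, 1174.3 and 1124.7. Quantile normalization removes such a difference between arrays. Between 46.9% and 49.5% of the 47231 probes lay above the estimated background of an array, and the number of arrays limits the precision. Pearson's r across genes, which are not independent replicates, was 0.971 to 0.991 within the parental group, 0.990 to 0.993 within the resistant group and 0.877 to 0.889 between the groups. Parental replicate 3 stood apart from the other parental arrays, at -35.78 on the second principal component against 11.5 and 22.51.

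The comparison asked which transcripts differed between parental and SINE-resistant cells while both were under the drug. Some transcripts at or near background in parental cells were abundant in resistant cells. Rises and falls are differences of resistant from parental cells, not changes over time. CAVIN2, which encodes a caveolar coat protein, rose from 5.09 ± 0.05 to 13.53 ± 0.14 (normalized log2 intensity, SD, n = 3 each), at least 277-fold. IGFBP3, which binds insulin-like growth factors, rose 256-fold from a level above background on 1 of 3 parental arrays (5.28 ± 0.26 to 13.28 ± 0.22, SD, n = 3 each), and the tight junction gene CLDN1 rose at least 88.2-fold. Among decreases, the secreted WNT antagonist DKK1 fell by 7.89 ± 0.17 on the log2 scale (SE), and the cyclin-dependent kinase inhibitor CDKN1A fell from 13.90 ± 0.19 to 7.12 ± 0.14 (SD, n = 3 each), 110-fold in the probe used (log2 fold change -4.25 as the mean over its 2 probes, against -6.78). Tested with limma and Benjamini-Hochberg adjustment, CAVIN2 had an adjusted p of 6.06e-11, DKK1 of 1.62e-10 and CDKN1A of 3.26e-10, and all 3 arrays of one group lay beyond all 3 of the other for each.

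The other large increases were those of ISL1, a LIM-homeodomain transcription factor (84.5-fold), TM4SF1 (at least 73.1-fold), POSTN, the matrix protein periostin (76.9-fold), MID1 (from 5.30 to 11.46 in the probe used), NRG1, a ligand of ERBB receptors (at least 35.7-fold), the collagen-modifying enzyme gene P3H2 (64.3-fold) and the interferon-inducible GTPase gene GBP1 (48.9-fold). The MID1 probe used was not above background on any parental array, so its fold change is not given, while another MID1 probe was above it on 2 of them, and without resistant replicates 1, 2 or 3 that other probe was used and the MID1 change was 3.10, 2.80 or 2.72. The other large decreases were those of ITM2A (129-fold), the neuropeptide genes NTS (93-fold) and VIP (at least 53.8-fold), MAP1LC3A (at least 47.3-fold), TCIM (at least 43.1-fold), TCEAL8 (at least 47.8-fold), the melanin synthesis gene TYRP1 (68.9-fold) and S100A4 (65.9-fold). These 15 genes had adjusted p-values between 2.82e-10 and 3.28e-09 in limma. "At least" marks a gene whose probes were not above background on any array of the dimmer group, and the bound uses the lowest signal above background there. Folds of genes above background on only 1 or 2 arrays of the dimmer group are less certain in size, here IGFBP3, GBP1, P3H2, ITM2A and TYRP1, and among genes named further on BIRC5, CXCL1, RRM2, JUN, NUP98, GRB7, NRG4, PHLDA3, KRT18, SNAI2, COL6A2, DKK3, BMP7, LIN28A, ALDH1A1, IFI44 and ESAM. CLDN1, CDKN1A and TCIM are among the genes whose probe identifiers had to be repaired before they could be named.

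**Figure D1:**
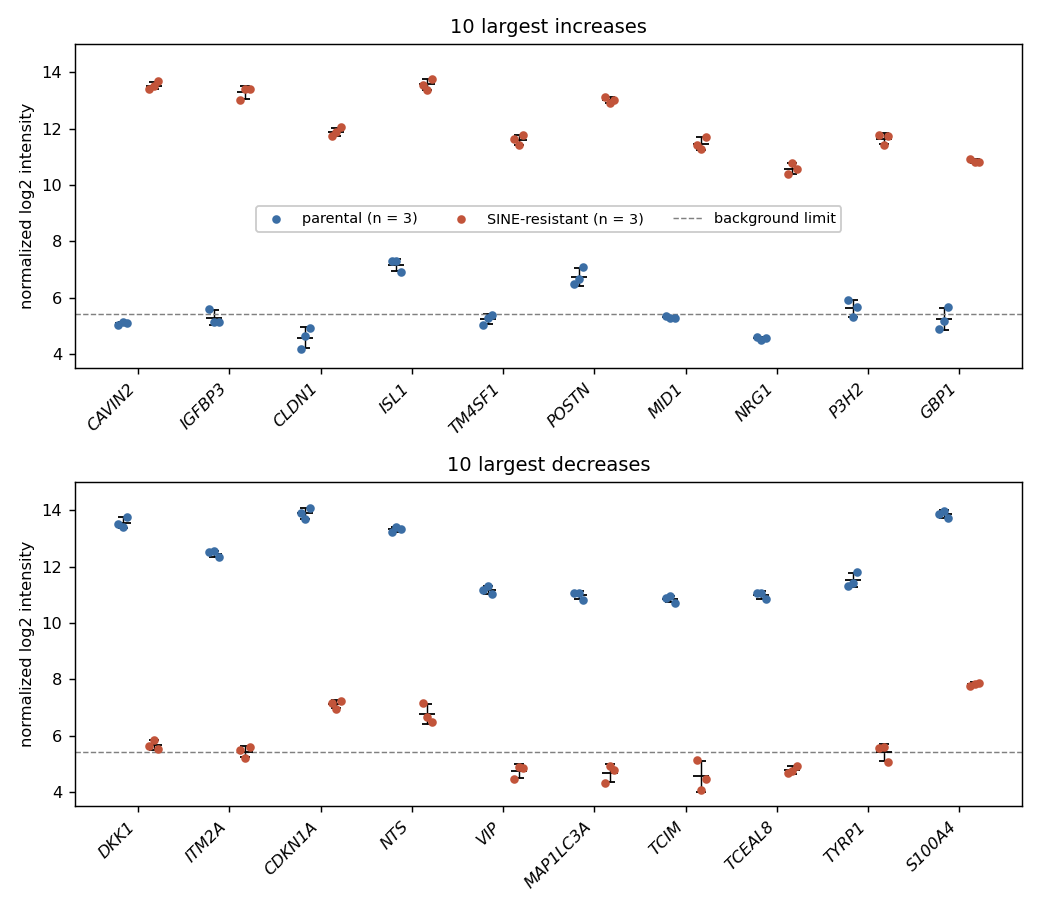
Normalized log2 intensity of the 10 genes with the largest increase (top) and the 10 with the largest decrease (bottom) in SINE-resistant cells, ranked by the difference of measured means. Genes below background in the dimmer group have a bound only, so their rank is not certain. Points are single arrays, bars the mean ± SD of 3 arrays, and the dashed line the lowest normalized value above background (5.42); the arrays of the groups do not overlap for any of these 20 genes.

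Over all 12590 genes tested, 2834 were higher and 2650 lower in resistant cells at an adjusted p under 0.05 (limma, Benjamini-Hochberg), which is 43.6% of the genes. Of these, 1211 were higher and 1103 lower by at least 2-fold, and 173 and 114 by at least 8-fold. The arrays of the groups did not overlap for 6680 genes (53.1%), against 10% by chance. A total of 318 genes were above background on all 3 resistant arrays and on no parental array, and 239 genes showed the opposite. The split of higher and lower calls rests on quantile normalization, with 51.7% higher here and 76.0% higher (4301 against 1359) when arrays were scaled to a common median, a change that moved the median of all genes by 0.27 on the log2 scale. The count of 2-fold changes was 1292 without background correction and 1450 in the authors' normalized values, against 2314 here.

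Cell division genes rose together in resistant cells, and most p53 target genes of the list fixed in advance fell. Every one of the 37 mitosis genes tested was higher, with a median log2 fold change of 2.90. DLGAP5 rose 26.6-fold, NUSAP1 24.4-fold, UBE2C 24.1-fold (3.05 on the log2 scale as the mean over its probes, against 4.59) and the DNA topoisomerase gene TOP2A 23.4-fold. Of 34 genes of DNA replication and the G1/S transition, 30 were higher, none was lower and 4 did not pass, with a median of 2.12. CDC45 (28.9-fold) and MCM10 (25.7-fold), which act in the start of replication, led this list, followed by E2F2 (log2 fold change 3.86) and RRM2 (3.84). Adjusted over the list alone, 37 mitosis genes were higher, and 30 replication genes were higher and 1 lower.

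Of 33 p53 target genes, none was higher, 31 were lower and 2 did not pass, with the same counts adjusted over the list alone. Their median log2 fold change was -1.65, or -1.60 with genes below background at their bound. These counts hold for the listed genes only, since the list does not hold every p53 target. PMAIP1 and IGFBP3, which are not on it, rose. After CDKN1A, the largest decreases were those of GDF15, a secreted stress cytokine (64.7-fold), PHLDA3 (13.5-fold) and the pro-apoptotic gene BAX (10-fold, or -1.97 on the log2 scale as the mean over its probes, against -3.33), and MDM2, which encodes a ubiquitin ligase, fell 3.38-fold. The 2 members that did not pass, named after their values were seen, were FAS (log2 fold change 0.26) and ZMAT3 (-0.04), and 2 other ZMAT3 probes were lower. In limma's camera test with a preset correlation of 0.01, the adjusted p was 2.51e-24 for mitosis, 4.56e-16 for replication and 6.05e-16 for p53 targets, and adjusted p = 0.0093, 0.0093 and 0.015 with an estimated correlation. Without parental replicate 3, in which the p53 list had a median 0.29 above that of the other parental arrays, 37 of 37 mitosis genes were higher and 29 of 31 p53 targets lower.

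**Figure D2:**
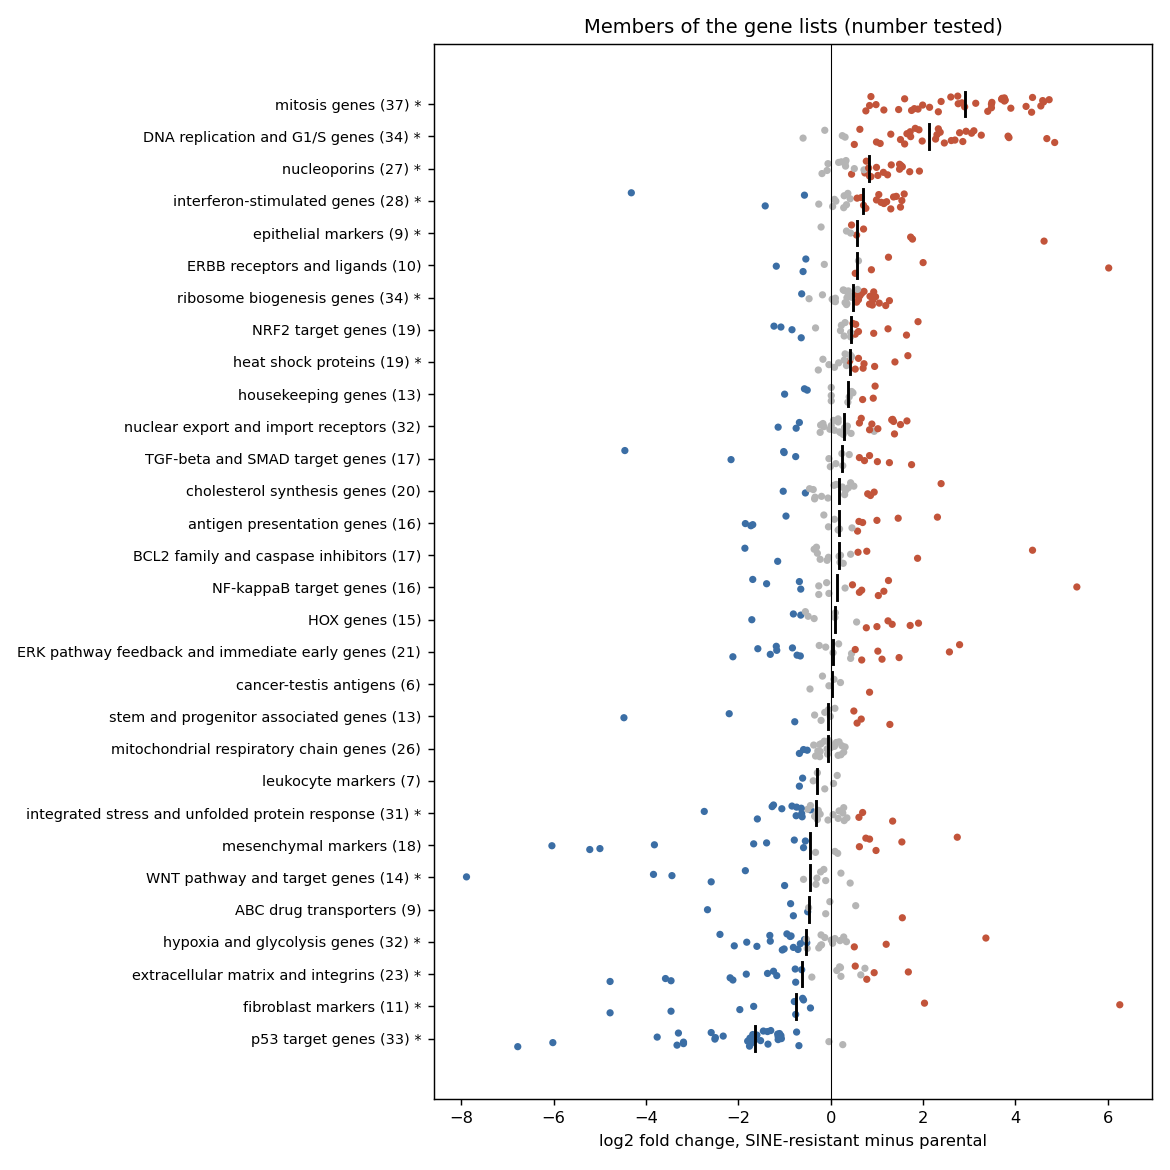
Log2 fold change (SINE-resistant minus parental) of each tested member of the 30 gene lists with at least 5 genes tested, with the number tested in brackets. Red points were higher and blue points lower at an adjusted p under 0.05, grey points did not pass, black bars are medians, and an asterisk marks an adjusted p under 0.05 in camera; the medians run from -1.65 for p53 targets to 2.90 for mitosis genes.

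Members of the ERBB receptor family and their ligands moved both ways. The study's later paper is remembered to concern NRG1 and ERBB3, so this list is not independent of the study. Of 10 genes tested, 5 were higher, 3 were lower and 2 did not pass, also when adjusted over the list alone, with a median of 0.56 (0.48 with genes at their bound) and a camera adjusted p of 0.203 (0.0382 with every probe on its own; range over the alternatives 0.0382 to 0.619). NRG1 was measured at 4.56 ± 0.05 in parental and 10.57 ± 0.19 in resistant cells (SD, n = 3 each, limma adjusted p = 3.81e-10), and all 3 of its probes were higher. The difference of measured means was 3.59 as the mean over its probes, against 6.02 in the probe used. Neither is a measured fold, since no NRG1 probe was above background on any parental array. ERRFI1, a feedback inhibitor of EGFR, rose 4.01-fold, the adaptor gene GRB7 2.38-fold and the receptor gene ERBB3 1.84-fold (adjusted p = 0.00478 in limma). The ligand gene NRG4 fell 2.27-fold. ERBB2 fell by 0.60 ± 0.21 (SE; limma adjusted p = 0.0361) and EGFR rose at least 1.29-fold (limma adjusted p = 0.0254). The ERBB2 call ended without parental replicate 1 (-0.53), parental replicate 3 (-0.48), resistant replicate 1 (-0.49) or resistant replicate 2 (-0.60) and under median scaling (-0.14), and the EGFR call ended without parental replicate 2 and with 4 other settings.

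Of 21 ERK feedback and immediate early genes, 7 were higher, 8 lower and 6 did not pass (8 and 8 adjusted over the list alone; camera adjusted p = 0.952). The AP-1 subunit gene JUN rose 6.93-fold and PHLDA1 5.92-fold, while SPRY4, which encodes a feedback inhibitor of the pathway, fell 4.36-fold and IER3 2.98-fold.

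**Figure D3:**
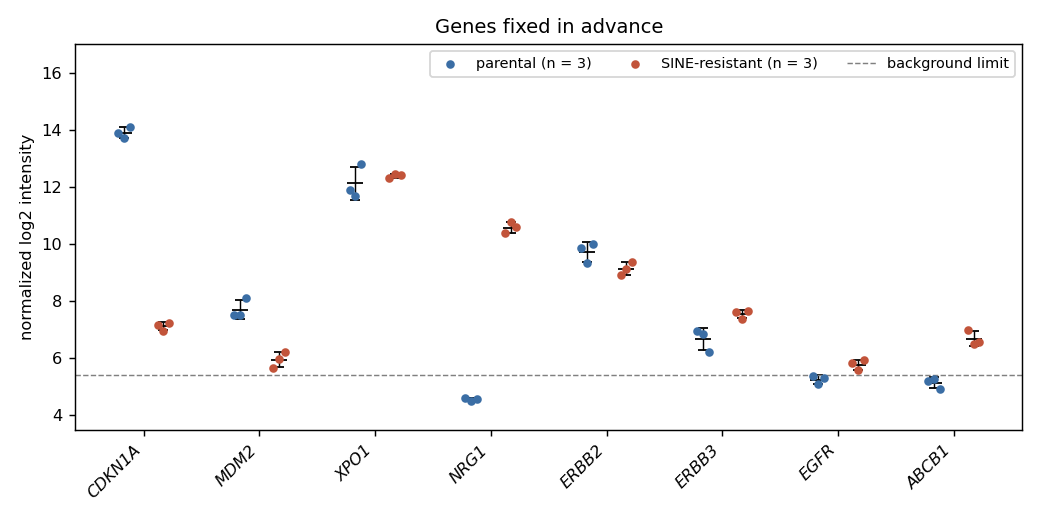
Normalized log2 intensity of 8 genes named before the data were examined. The study's later paper is remembered to concern NRG1 and ERBB3, so their choice is not independent of the study. Points are single arrays, bars the mean ± SD of 3 arrays, and the dashed line the lowest normalized value above background (5.42); CDKN1A and NRG1 differ most, and the XPO1 values of the groups overlap.

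Components of the nuclear pore were higher in resistant cells, and XPO1, the drug's target, did not pass the test. XPO1 was measured at 12.12 ± 0.58 in parental and 12.40 ± 0.07 in resistant cells (SD, n = 3 each), a difference of 0.27 ± 0.25 (SE; limma adjusted p = 0.412). Parental replicate 3 lay at 12.79 and the other parental arrays at 11.9 and 11.69; without parental replicates 1 and 2 the difference was 0.16 and 0.05, and without replicate 3 it was 0.61 (limma adjusted p = 0.00462; range over the alternatives 0.00397 to 0.888). Of 27 nucleoporin genes, 17 were higher, none was lower and 10 did not pass (18 higher adjusted over the list alone), with a median of 0.82. NUP107 rose 3.79-fold, NUP98 3.27-fold in 1 of 3 probes (log2 fold change 0.64 as the mean over its probes, against 1.71), NUP210 2.93-fold and NUP35 2.88-fold. Camera gave an adjusted p of 2.33e-05, and adjusted p = 0.21 with an estimated correlation.

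Of 32 genes of export and import receptors and the Ran cycle, 11 were higher, 3 lower and 18 did not pass, the same adjusted over the list alone, with a camera adjusted p of 0.0658. RANBP2 rose 3.14-fold, CSE1L, the exporter of importin alpha, 2.6-fold and RANBP1 2.57-fold. IPO7 rose by 1.51 ± 0.45 (SE), a call that ended when parental replicate 1 (1.42), parental replicate 2 (0.97), resistant replicate 2 (1.46) or resistant replicate 3 (1.32) was left out. In parental replicate 3 this list had a median 0.38, and the nucleoporins a median 0.31, above the other parental arrays. The receptor list passed camera without parental replicate 3 (adjusted p = 0.0101), without parental replicate 1 (0.0484) and without resistant replicates 1, 2 or 3 (0.0385, 0.0425 and 0.0458), but not without parental replicate 2 (0.113). In all it passed in 12 of 19 alternatives, among them median scaling (camera adjusted p = 0.0295), 75th percentile scaling (0.0186), no filter (0.0186) and array weights (0.0411). With an estimated correlation, which is not among these 19, its camera adjusted p was 0.53.

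Of 9 epithelial markers tested, 6 were higher, none was lower and 3 did not pass, the same adjusted over the list alone, with a median of 0.56 (0.43 with genes at their bound). The adhesion gene EPCAM rose 24.5-fold, KRT8 at least 2.69-fold, KRT18 3.31-fold and ELF3 at least 1.42-fold. Only 3 of the 9 were higher under 75th percentile scaling, without background correction and in the authors' values, and the ELF3 call ended in these settings (limma adjusted p = 0.112, 0.0595 and 0.0528). In camera the list had an adjusted p of 0.00711, and adjusted p = 0.16 with an estimated correlation. Of its 9 genes, 5 were below background on every array of 1 group and have a bound only. The list could be tested in 15 of 19 alternatives. It had too few genes for camera when only genes above background on all 6 arrays were kept. Of 18 mesenchymal markers, 6 were higher, 9 lower and 3 did not pass, the same adjusted over the list alone. The decreases of S100A4, the transcription factor genes SNAI2 (37.4-fold) and TWIST1 (32-fold) and the receptor gene AXL (14.1-fold) were the largest of this list. The list's median was -0.44, with a median 0.29 higher in parental replicate 3 than in the other parental arrays, and its camera adjusted p 0.146, which became 0.0459, 0.0406 and 0.0274 without resistant replicates 1, 2 and 3, 0.0295 under median scaling and 0.0455 with every probe on its own (range over the alternatives 0.0274 to 0.385).

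Of 23 extracellular matrix and integrin genes, 4 were higher, 12 lower and 7 did not pass (6 higher and 12 lower adjusted over the list alone), with a median of -0.63. COL1A2 fell 27.5-fold, COL6A1 11.9-fold, COL3A1 11-fold and COL6A2 4.55-fold (-1.18 on the log2 scale as the mean over its probes, against -2.18). For this list camera's adjusted p was 0.0396, and adjusted p = 0.68 with an estimated correlation; it was 0.241 without parental replicate 3, in which the list had a median 0.43 above the other parental arrays, and 0.0546 and 0.0636 without resistant replicates 1 and 2. The list's call ended in 9 of 19 alternatives, among them no background correction (camera adjusted p = 0.0762), the authors' values (0.066), no filter (0.0796) and array weights (0.111), with a range of 0.00785 to 0.241 over all 19, and it was 0.81 with identifiers as deposited. Of 11 fibroblast markers, 2 were higher and 9 lower, the same adjusted over the list alone, with a median of -0.76 (camera adjusted p = 0.0235, 0.055 without parental replicate 3, and adjusted p = 0.32 with an estimated correlation). POSTN and the smooth muscle actin gene ACTA2 (4.08-fold) rose while COL1A2 and COL3A1 fell, so the markers of this other cell type moved apart. Of 7 leukocyte markers, none was higher and 2 were lower, CD68 (1.6-fold) and FCGR3A (1.53-fold), and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.373; median -0.41 in parental replicate 3 against the other parental arrays). As the mean over its probes CD68 stood at -1.40, against -0.68. The CD68 call ended without parental replicate 1 (-0.64), parental replicate 2 (-0.57) or resistant replicate 2 (-0.52), the FCGR3A call without resistant replicate 2 (-0.54) and as the mean over its probes (-0.20), and both under median scaling. The 1 endothelial marker tested, ESAM, rose 1.58-fold, a call that ended without resistant replicate 2 (0.61) or 3 (0.63) and under 75th percentile scaling (0.42).

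Of 14 WNT pathway and target genes, none was higher, 6 were lower and 8 did not pass, the same adjusted over the list alone, with a median of -0.45. Besides DKK1, these included SFRP1 (at least 11.7-fold), DKK3 (10.8-fold) and NKD2 (6.01-fold), all of which encode inhibitors of the pathway or members of inhibitor families. The WNT list had a camera adjusted p of 0.00164, and adjusted p = 0.37 with an estimated correlation, and a median 0.36 above the other parental arrays in parental replicate 3. Of 17 TGF-beta and SMAD target genes, 6 were higher, 5 lower and 6 did not pass, the same adjusted over the list alone, with a median of 0.24 (0.12 with genes at their bound), a mean of -0.13 and a camera adjusted p of 0.757. The ligand gene BMP7 fell 21.9-fold and TGFB2 at least 3.26-fold, while SKIL rose 3.35-fold and ID1 2.42-fold.

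Interferon-stimulated genes were mostly higher. Of 28 tested, 16 were higher, 3 lower and 9 did not pass, the same adjusted over the list alone, with a median of 0.69 (0.42 with genes at their bound). PARP9 rose 3.01-fold, OAS3 2.91-fold and IFI44 2.86-fold, whereas BST2, which encodes the virus-tethering protein tetherin, fell 19.9-fold. The camera adjusted p was 0.00388, and adjusted p = 0.12 with an estimated correlation. Of 16 antigen presentation genes, 6 were higher, 4 lower and 6 did not pass (7 and 4 adjusted over the list alone; camera adjusted p = 0.606; median -0.37 in parental replicate 3 against the other parental arrays). The immunoproteasome gene PSMB9 rose in the probe used (4.73 to 7.05), which was not above background on any parental array, so its fold change is not given; its log2 change in another probe was 0.64 without resistant replicate 1, and 0.53 and 0.54 without replicates 2 and 3, which did not pass. The class II genes HLA-DPA1 (3.61-fold), HLA-DRB1 (3.33-fold) and HLA-DMA (3.23-fold) fell. Of 16 NF-kappaB target genes, 7 were higher, 4 lower and 5 did not pass, the same adjusted over the list alone, with a camera adjusted p of 0.548. The chemokine gene CXCL1, above background on 1 parental array, rose 40.3-fold and SOD2 2.39-fold, and PLAU fell 3.23-fold and VCAM1 at least 1.94-fold.

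Of 32 hypoxia and glycolysis genes, 3 were higher, 16 lower and 13 did not pass (3 and 17 adjusted over the list alone), with a median of -0.53; under median scaling 5 were higher and 10 lower, with a median of -0.11, or -0.38 relative to the median of all genes. ANKRD37 fell 5.27-fold, the glucose transporter gene SLC2A3 4.25-fold and PFKFB4 3.53-fold, while the enolase gene ENO2 rose at least 7.94-fold. The camera adjusted p was 0.0133, and adjusted p = 0.37 with an estimated correlation. Of 34 ribosome biogenesis genes, 16 were higher, 1 lower and 17 did not pass, the same adjusted over the list alone, with a median of 0.49. NOLC1 rose 2.42-fold, NOP56 2.28-fold and GAR1 2.07-fold. The camera adjusted p was 0.00164, and adjusted p = 0.12 with an estimated correlation. Of 19 heat shock protein genes, 8 were higher, none was lower and 11 did not pass, the same adjusted over the list alone, with a median of 0.42; CHORDC1 rose 3.19-fold, HSPB1 2.61-fold, HSPH1 1.93-fold and HSP90AA1 1.65-fold, the last a call that ended under 75th percentile scaling (0.39). The camera adjusted p was 0.022, 0.0655 without parental replicate 2, and adjusted p = 0.37 with an estimated correlation.

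Of 31 genes of the integrated stress and unfolded protein responses, 3 were higher, 12 lower and 16 did not pass (3 and 13 adjusted over the list alone). HSPA5, the main chaperone of the endoplasmic reticulum, fell 6.68-fold, DDIT4 3.01-fold and CRELD2 2.42-fold, while the transcription factor gene ATF3 rose 2.53-fold. The median was -0.33, and 0.01 under median scaling. The camera adjusted p was 0.0469, and adjusted p = 0.37 with an estimated correlation; it was 0.0639, 0.0636 and 0.0518 without resistant replicates 1, 2 and 3, and 0.221 and 0.174 under median and 75th percentile scaling (range over the alternatives 0.0172 to 0.221, and 0.0119 with identifiers as deposited). Of 19 NRF2 target genes, 8 were higher, 4 lower and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.221), with PIR 3.7-fold and GCLM 3.12-fold higher (GCLM in 1 of 2 probes, with 0.64 as the mean over its probes against 1.64) and AKR1C3 2.35-fold lower. Of 20 cholesterol synthesis genes, 4 were higher, 2 lower and 14 did not pass, the same adjusted over the list alone (camera adjusted p = 0.548), with STARD4 5.25-fold higher and TM7SF2 2.05-fold lower.

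The drug efflux pump gene ABCB1 rose at least 2.42-fold, from 5.14 ± 0.18 to 6.69 ± 0.26 (SD, n = 3 each; limma adjusted p = 4.11e-05). It was the only one of 9 ABC transporter genes tested to be higher; 4 were lower and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 0.273), while under median scaling 2 were higher and 1 lower. With a resistant array left out ABCB1 was above background on too few arrays to be tested. The same held for other genes above background in resistant cells only, among them CAVIN2, CLDN1, TM4SF1 and NRG1. With a parental array left out it held for genes above background in parental cells only, such as VIP. ABCA1, a cholesterol exporter, fell 6.37-fold, and the calls for ABCB6 (1.83-fold lower) and ABCC4 (1.75-fold lower) ended under median scaling. Of 17 BCL2 family and caspase inhibitor genes, 4 were higher, 2 lower and 11 did not pass, the same adjusted over the list alone (camera adjusted p = 0.659). BIRC5, which encodes survivin and is also in the mitosis list, rose 20.6-fold and the pro-apoptotic PMAIP1 3.69-fold in the probe used. Without parental replicates 1, 2 or 3 the other PMAIP1 probe was the brighter. The PMAIP1 change was then 3.61, 3.73 or 3.17 on the log2 scale, against 1.88 with all arrays. CFLAR, an inhibitor of caspase 8 activation, fell 3.64-fold and BCL2L2 2.21-fold.

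Of 13 stem and progenitor associated genes, 4 were higher, 3 lower and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 0.606). The RNA-binding protein gene LIN28A fell 22.3-fold and NES 4.6-fold, while ALDH1A1 rose 2.42-fold. Of 15 HOX genes, 6 were higher, 3 lower and 6 did not pass (7 and 3 adjusted over the list alone; camera adjusted p = 0.475; median -0.41 in parental replicate 3 against the other parental arrays), with HOXB6 3.74-fold in 1 of 2 probes (log2 fold change 0.68 as the mean over its probes, against 1.90), HOXB4 3.3-fold and HOXB5 2.52-fold higher and HOXC4 3.27-fold lower. The ovarian and Mullerian lineage list had 4 genes tested, too few for camera; FOLR1 fell at least 3.48-fold and FOXL2 2.2-fold, and 2 did not pass, the same adjusted over the list alone. Of 6 cancer-testis antigens, MAGEA4 was at least 1.19-fold higher, a call that ended without background correction, and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.884).

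Of 26 respiratory chain genes, 3 were lower and 23 did not pass (1 lower adjusted over the list alone; camera adjusted p = 0.47). These were NDUFB5 (1.6-fold), SDHC (1.5-fold) and SDHA (1.43-fold), whose calls all ended under median scaling. The SDHC call also ended without any one of the arrays other than parental replicate 3 (-0.62 to -0.47), and the SDHA call without parental replicate 1 (-0.54), resistant replicate 2 (-0.44) or resistant replicate 3 (-0.49). Of 13 housekeeping genes, 3 were higher, 3 lower and 7 did not pass (5 and 3 adjusted over the list alone; camera adjusted p = 0.47). TUBB rose 1.94-fold, TBP 1.9-fold and B2M 1.61-fold, and PPIA fell 2-fold; the B2M call ended under 75th percentile scaling (0.45). In all, 13 of the 30 lists tested passed camera with the preset correlation, and the mitosis, replication and p53 lists were the 3 that passed with an estimated one.

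**Figure D4:**
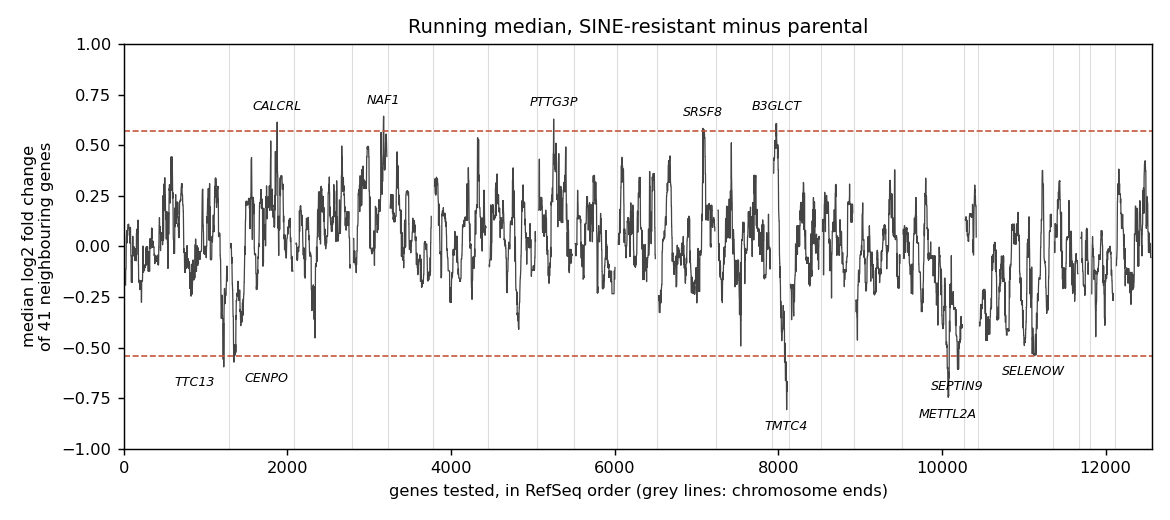
Median log2 fold change (SINE-resistant minus parental) of 41 neighbouring genes along the 12572 genes in RefSeq order, with chromosome ends as grey lines and the centre gene of each run beyond the limits named. The dashed lines are the limits from 10000 shuffled gene orders (-0.54 and 0.57); 6 runs lie below and 5 above them, and the lowest median, -0.81, is centred on TMTC4.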

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

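Scaling to the 75th percentile and the deposited identifiers were chosen after the result was seen. The cause of the differences below was not tested except where the setting itself shows it. Median scaling gave 4301 higher and 1359 lower genes and moved the median of all genes by 0.27; relative to that median, the p53 list lay at -1.51 and the mitosis list at 3.01. Array weights gave 4028 lower genes (4193 higher), with 5461 of the 5484 calls kept. Genes changed at least 2-fold numbered 1292 without background correction and 1450 in the authors' log2 values, both of which compress the changes of dim genes. The number of lists shifted was 3 with an estimated correlation and 23 with fry, which does not compare a list with other genes. With 1 array left out, higher genes numbered 1935 to 3557, lower genes 1922 to 3026, 2-fold changes 2044 to 2411 and lists 12 to 14. Genes above background in 1 group only were not tested when an array of that group was left out. The highest of the gene counts came without parental replicate 3. Replicate numbers did not pair the arrays, since deviations of same-numbered arrays correlated at 0.03, -0.01 and -0.02; with the replicate number as a block, 2735 genes were higher, 2550 lower and 2314 changed 2-fold, with 5187 calls shared and 13 lists shifted.

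Over 2578 values of 135 named genes, those with the deposited identifiers included, 2525 kept direction and side of the threshold, 50 lost the call, 2 (both XPO1: 0.49 with array weights, 0.61 without parental replicate 3) gained it and 1 reversed. Every probe on its own, the trended variance model and the replicate block could not change the fold change of the brightest probe. Genes that a setting did not test are not counted, so only 93 named genes entered with the filter on all 6 arrays. With identifiers as deposited, COL6A2 stood at 0.52 (limma adjusted p = 0.0511; 2.34e-09 to 0.000743 over the other alternatives) in place of -2.18, because that identifier named another probe's values. That setting tested 10390 genes and lost 2333, of which 1057 had been called, among them CDKN1A, CLDN1, BAX, CDC45, BIRC5, COL1A2 and ABCB1, and 13 called genes were called in the opposite direction. The mean over a gene's probes in place of the brightest gave smaller changes for NRG1 (3.59), CDKN1A (-4.25), BAX (-1.97), UBE2C (3.05), NUP98 (0.64), HOXB6 (0.68), GCLM (0.64) and COL6A2 (-1.18), in the same direction, and a larger one for CD68 (-1.40). The NRG1 value is a difference of measured means only, since no NRG1 probe was above background on any parental array. Under 75th percentile scaling the calls for EGFR, ERBB2, ELF3, ESAM, HSP90AA1, B2M, SDHA and SDHC ended. The other counts kept within 1.5 times. A slide block was not run because the files name no slide. Changes of genes near background are the least certain in size: 557 genes have only a bound, and list medians with these at their bound moved for 6 lists, by at most 0.26.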

Other observations

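The genes of the first paragraphs and all tests except those on other splits of the arrays and 2 of those on neighbouring genes (array parental 3 for the 2 lowest runs, and copy number) were chosen after the result was seen. The matrix metalloproteinase genes MMP1 and MMP3 rose by 4.88 ± 0.19 and 4.51 ± 0.17 on the log2 scale (SE), 29.4-fold and 22.7-fold. ANXA1 rose at least 24.3-fold, ANXA3 at least 15-fold and the fatty acid receptor gene CD36 at least 21.5-fold. The growth factor gene MDK, midkine, rose 47.7-fold, and TNFRSF19 43-fold. The highest adjusted p of these genes in limma was 4.32e-09, that of TNFRSF19, and all 3 resistant arrays lay above all 3 parental arrays for each.

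UCHL1, a neuronal deubiquitinase gene, fell 50.3-fold, the proteoglycan gene VCAN at least 38.8-fold, HAPLN1, which encodes a link protein of such proteoglycans, 64.9-fold, and the membrane metalloendopeptidase gene MME at least 27.9-fold. The protocadherin gene PCDH20 fell at least 38-fold and the oestrogen-metabolising enzyme gene CYP1B1 49.8-fold. TCEAL3 fell at least 21.4-fold, as its relative TCEAL8 did by at least 47.8-fold. The highest adjusted p of these genes in limma was 5.71e-08, that of MME.

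The other 9 of the 10 splits of the 6 arrays into 3 and 3 gave 0 genes past limma's test, against 5484 for the real split, with 18 to 402 genes at an unadjusted p under 0.05. For 2-fold changes the real split gave 2314 and the highest other 0. For gene lists the real split gave 13 and the highest other 10. In each case 1 split of 10, the real one, gave a result as large, and 10 splits are too few for a share under 0.05. Every other split mixes both lines in each group. The difference between the lines then adds to the spread within groups, which holds gene calls down, and part of it remains in the list tests. These splits are thus no measure of what arrays without a difference would give.

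The lower p53 targets and higher mitosis genes of resistant cells were weighed first. Scaling of the arrays is argued against, since the p53 list's median was -1.17 with the arrays not scaled to each other, and -1.25 and -1.59 with a single factor per array (median and 75th percentile), while the mitosis list's was 3.36, 3.28 and 2.94. Parental replicate 3 alone is argued against, since the p53 median was -1.55 without it. It stays open whether the resistant state itself, or a weaker action of the drug in resistant cells during the 24 h exposure, may account for the pattern. XPO1, whose mRNA is known to rise under these drugs, differed by 0.27 and decided neither way, and the effects of drug and resistance cannot be told apart without drug-free arrays of both lines. Nor can these arrays tell resistance apart from other differences between the parental line and its derivative.

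Parental replicate 3 differed from the mean of the other parental arrays by over 1 log2 unit in 413 genes. The difference rose with gene length across genes (Spearman's rho 0.36; genes are not independent replicates). The same rho was 0.10 for parental replicate 1 minus replicate 2 and between -0.05 and 0.09 for resistant arrays against their group. A yield of RNA or label that depends on gene length is a candidate explanation that these values go with but do not show. No such yield was examined here, and no biological explanation other than the next was tested. A shift toward the resistant state as the whole cause is argued against, because the p53 list lay 0.29 above the other parental arrays where resistant cells were lower, although the mitosis list (0.16) and the nucleoporins (0.31) moved the way of resistant cells. On the first principal component, parental replicate 3 was also the parental array nearest the resistant ones. It lay at -52.72, against -59.27 and -57.66 for the other parental arrays and 55.44 to 58.45 for resistant arrays.

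Neighbouring genes shifted together. Among 12572 genes in RefSeq order, the lowest running median of 41 neighbours was -0.81, and the share of 10000 shuffled orders with one as low was 1e-04, the smallest they can give, which argues against a chance order. The highest median was 0.64 (permutation p = 0.0043 from the same shuffles). Beyond the limits from the shuffles (-0.54 and 0.57) lay 6 lower and 5 higher runs. The lowest were TDRD3 to CHAMP1 (72 genes, 40 called lower, 9 higher) and MKS1 to PITPNC1 (65 genes, 32 called lower, 5 higher), which holds the p53 target PPM1D.

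For those 2 runs, the test of array parental 3 set in advance did not decide. Their medians over the runs were -0.49 and -0.48 without it, against -0.65 and -0.51 with all arrays. Both lie between the bounds set for and against it (0.3 and 0.5 below 0). A run at -0.51 with all arrays had little room to stay beyond the bound of 0.5. Most of the shift of both runs remained without the array, which argues against it as their whole source. The other lower runs had medians of -0.63 to -0.36 without it, against -0.59 to -0.52 with all arrays. For the 5 higher runs array parental 3 is argued against, since their medians without it were 0.59 to 0.78, against 0.49 to 0.66 with all arrays. A lower copy number in resistant cells may be the source of the 2 lowest runs, as their brighter genes were lower too (medians -0.82 and -0.62), but no DNA was measured, so copy number and shared regulation cannot be told apart. In 2 higher runs the brighter genes moved less than the run, CHORDC1 to ZC3H12C (0.31 against 0.49) and WASF3 to FOXO1 (0.17 against 0.54). In the other higher runs the brighter genes had medians of 0.61 to 0.64. Other lower runs hold the p53 targets TP53I3, BBC3 and BAX, which fell, and the mitosis genes CENPA and BIRC5, which rose by 3.48 and 4.37 against their runs.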
